A study of Listeria monocytogenes with 30 samples.

How the data were processed

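RNA sequencing of Listeria monocytogenes FS2025, a serotype 1/2b strain, was analysed in 4 groups. Planktonic cells had grown without shaking for 48 h at 24 °C in 1X cantaloupe juice or in 1X tryptic soy broth (TSB, a rich laboratory medium). Biofilm cells were sonicated off steel coupons on day 3 in 0.5X of the same media. Growth form therefore goes together with harvest time, medium strength and sonication, and none of these can be separated from it. Per the labels, each group came from 3 independent experiments, with 2 technical replicates per planktonic culture and 3 per biofilm culture, 30 samples in all. The deposited data were 12 tables, 1 for each group and experiment number. How the technical replicates were joined is not given in the sources used here.

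Per the labels' protocols, total RNA went through ribosomal RNA depletion and a stranded library kit. Per the submitters' processing notes, FastQC and Salmon 1.9.0 were used. Per the file headers, each deposited table gives estimated counts and TPM (length-scaled read shares) for 3019 rows. The expected counts were deposited without normalization, and the TPM values were scaled by Salmon, per the file headers, over every row including rRNA and small RNA. The genome build, the Salmon options and any trimming are not given in the sources used here. All 3019 row names matched locus tags in a reference gene table of strain EGD-e, and 3016 row lengths equalled those in that table. EGD-e is a different strain from FS2025, so genes that only FS2025 carries were not measured, and genes that differ in sequence may be undercounted. That table gives symbols and kinds of RNA but no products and no strand. The rows were 2866 protein-coding genes, of which 608 have a symbol, 99 small RNA rows, 9 rRNA rows and 45 tRNA rows.

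A single table had been deposited under 2 names, as cantaloupe juice biofilm 3 and as TSB biofilm 1, and the 2 copies were identical in every value. Which group it belongs to was not decided from its values. Its Spearman correlation over protein-coding genes was 0.962 and 0.963 with the TSB biofilms and 0.909 and 0.917 with the juice biofilms, and the 4 small RNA rows described with the depths held 0.0559% of its reads, as in the low class. It was left out of both groups in the main comparisons, which departs from the plan made before the data were examined (all 12 tables). The comparisons thus rest on 10 libraries, 3 for each planktonic group and 2 for each biofilm group. No other pair of tables within a group agreed within sampling noise.

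The estimated counts were rounded to whole numbers. Rows for rRNA and tRNA were left out of library sizes and tests. Of the remaining 2965 rows, 2668 passed the edgeR filter on low counts (filterByExpr with the groups), 2595 of them protein-coding. Libraries were scaled by TMM, with factors from 0.364 to 2.7, and CPM values are counts per 1e6 on these scaled sizes, as mean ± SD with n = 3 for planktonic and n = 2 for biofilm groups. The main test was edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) in edgeR 4.0.16 with R 4.3.3, on 1 fit of the 4 groups without covariates. Its adjusted p-values are Benjamini-Hochberg over all rows tested, with a threshold of 0.05. The biological coefficient of variation was 0.562. The 5 comparisons were fixed before the data were examined, namely the medium effect in each growth form, the growth form effect in each medium, and the interaction of both. Log2 fold changes are given ± their standard errors, the latter computed from the fold change and the F statistic.

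A set of 25 gene lists was fixed before the data were examined and tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over all lists and the 5 comparisons together. Each list needed 4 tested genes. After the first fits, 6 entries were seen to be other genes with the same symbol or a mistyped tag, such as lmo2543, which shares the symbol prfA but encodes a peptide release factor. The lists were kept as written, and a version without these entries was run as an alternative. Of the 50 calls by camera none held with an estimated correlation, which is why that p is printed beside each call.

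The named genes follow a rule fixed before the data were examined. For each of the first 4 comparisons it takes the 10 largest rises and 10 largest falls past the threshold whose libraries did not overlap between the groups and whose mean was at least 10 CPM in the higher group. For the interaction it takes 5 and 5 without the condition on overlap. It adds up to 3 members with the smallest adjusted p from each called list, and a set of well-known genes. Of that set, mogR, degU, agrA, luxS, bapL and pduC are not symbols in the reference table, so no value is given under those names.

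The procedure was tested on simulated counts with the real library sizes and spread, in which 200 genes were changed. In the planktonic comparison, 42% of genes changed 4-fold and 87.9% of those changed 16-fold were recovered. In the biofilm comparison, 10.3% and 75.3% were recovered. Of the calls, 2.3% and 2.4% were unchanged genes. These rates describe the simulated counts. The real libraries also deviated together across genes, with correlations up to 0.572 between same-numbered planktonic libraries. Recovery and false calls under such shared deviations were not tested, so the rates may not carry over to the real data.

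Same-numbered planktonic libraries, by the numbers in the table names, deviated together from their group means, with correlations across genes of 0.108, 0.452 and 0.572. All exceed 0.1, the rule used for pairing, so a replicate block was run beside the unblocked fit. The support is weak, since juice replicate 1 went further with TSB replicate 2 (0.467) than with TSB replicate 1, and deviations of 3 libraries sum to about 0, so the 3 values are not independent. Biofilm libraries shared too few numbers with the others for such a decision.

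Alternatives planned before the data were examined were other scaling factors, other filters, DESeq2 1.42.0, limma on log2(TPM + 1), the replicate block, rRNA and tRNA rows kept, each library left out, and fits on only the groups compared. Chosen after seeing the data were the 3 uses of the duplicated table, protein-coding rows alone, a term for the library class described with the depths, and a planktonic comparison within the high class. Reads per table were 29.8 M to 71 M (M for 1e6), of which 3.98 M to 32.4 M fell on protein-coding rows, so counting error is small beside the spread between cultures for all but the weakest genes. Without a strand or a product in the reference table, overlapping and antisense genes could not be checked for shared reads. Salmon shares reads among near-identical genes by estimate, so members of such families are uncertain.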

Results

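Cells of a serotype 1/2b Listeria monocytogenes strain were compared between cantaloupe juice and TSB, as free planktonic cells and as biofilms on stainless steel, to see how a fruit matrix alters gene expression. The comparisons rest on 10 libraries, 3 from each planktonic group and 2 from each biofilm group. The 12 tables held between 29.8 M and 71 M reads. Protein-coding rows took 10.9% to 67.8% of reads, small RNA rows 28.1% to 82.1%, rRNA 1.74% to 9.12% and tRNA at most 0.102%. A single small RNA row, lmos81, held 2.26% to 80.0%.

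The libraries also fell into a pair of classes by 4 other small RNA rows, lmos53, lmos73, lmos89 and lmos95. These held 28.7% to 56.6% of reads in 6 libraries, namely the 3 planktonic and 2 biofilm cantaloupe libraries and planktonic TSB replicate 1. In the others they held 0.0546% to 0.0976%. The class thus nearly coincides with the medium. In biofilms it cannot be told apart from the medium, and in planktonic cells 1 TSB library breaks the overlap.

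**Figure D1:**
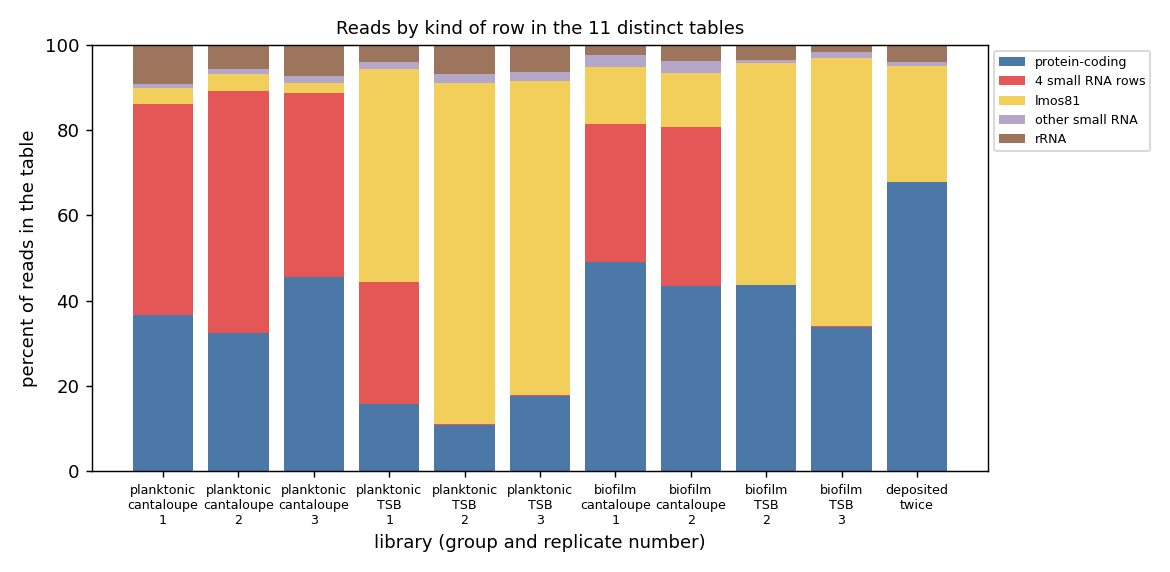
Percent of reads (y axis) by kind of row in the 11 distinct tables (x axis, group and replicate number). The 4 small RNA rows take 28.7% to 56.6% in 6 libraries and under 0.1% in the other 5, and the table deposited under 2 names stands last.

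In planktonic cells, lmo1634 and 33 of 56 ribosomal protein genes had higher transcript levels in cantaloupe juice than in TSB, and the manganese transporter genes lmo1847, lmo1848 and lmo1849 and the glutamate decarboxylase gene lmo2363 lower ones. The transcript of lmo1634, the bifunctional acetaldehyde-alcohol dehydrogenase, stood at 62860 ± 40630 CPM in juice (n = 3) and 243 ± 190.3 CPM in TSB (n = 3), a log2 fold change of 8.02 ± 1.07 (adjusted p = 0.00145). The lmo1848 transcript, part of a manganese ABC transporter, stood at 0.501 ± 0.209 CPM in juice and 91.6 ± 18.9 CPM in TSB, a log2 fold change of -7.55 ± 0.54 (adjusted p = 0.000241). The edgeR test called 629 of 2668 rows, 348 higher in juice and 281 lower. The split was 337 and 104 on log2(TPM + 1) values, 281 and 335 with upper-quartile factors, 653 and 727 without juice replicate 3, 84 and 130 with the class as a term and 47 and 99 within the high class, so which direction holds more genes is not settled.

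Among the largest rises, lmo0481 changed by 7.76 ± 0.88, lmo2095 by 7.54 ± 1.17 and lmo0752 by 5.79 ± 0.67 on the log2 scale. The ammonium transporter gene lmo1516 and the neighbouring nitrogen regulatory PII gene lmo1517 rose by 6.11 ± 0.68 and 7.63 ± 0.89, the latter from only 0.117 CPM. Further rises were lmo2580 at 5.26 ± 0.70, and lmo2361 at 5.30 ± 1.32 and lmo2829 at 5.29 ± 1.22, whose sizes came from juice replicate 3 and were 2.43 and 2.75 without it (adjusted p = 0.00802 and 0.00299). The call of lmo2361 was lost without TSB replicate 1 (adjusted p = 0.0648) or replicate 2 (0.0701), and that of lmo2829 without TSB replicate 1 (0.0504) or replicate 2 (0.0571). Large falls included lmo2586, a formate dehydrogenase gene, at -7.06 ± 0.71, and its neighbour lmo2585 at -6.84 ± 0.60. The cellobiose-type phosphotransferase genes lmo2684 and lmo2685 fell with log2 fold changes of -5.60 ± 0.70 and -5.84 ± 0.88, and lmo1999 with -5.88 ± 0.84.

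Of 56 ribosomal protein genes, 33 rose in juice and none fell, or 37 adjusted over the list alone (camera adjusted p = 1.19e-16, adjusted p = 0.209 with an estimated correlation). Examples were rpsN (lmo2619) at 4.51 ± 0.57, rplX at 4.58 ± 0.61 and rplE at 4.33 ± 0.58. Of 21 glycolysis and fermentation genes 9 rose, 11 adjusted over the list alone, with 1 fall there (adjusted p = 0.000135, adjusted p = 0.637 with an estimated correlation). The enolase gene eno changed by 4.01 ± 0.63 and the phosphoglycerate mutase gene pgm by 4.32 ± 0.70. Of 13 chaperone and Clp genes 6 rose by either adjustment, the second adjusted over the list alone (adjusted p = 0.0155, adjusted p = 0.651 with an estimated correlation). Examples were dnaJ at 3.79 ± 0.60, groES at 2.34 ± 0.50 and groEL at 2.91 ± 0.68. Of 56 amino acid biosynthesis genes 11 rose and 2 fell, and the same numbers adjusted over the list alone (adjusted p = 0.0141, adjusted p = 0.719 with an estimated correlation). The arginine synthesis genes argH and argG rose by 5.32 ± 0.73 and 4.17 ± 0.68, and trpF by 3.61 ± 0.71 from very low levels.

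Among 11 zinc and manganese uptake genes 5 fell and none rose, also adjusted over the list alone (adjusted p = 1.01e-05, adjusted p = 0.271 with an estimated correlation). Next to lmo1848, lmo1847 fell with -6.43 ± 0.49 and lmo1849 with -6.67 ± 0.68. In the acid resistance list 5 of 13 genes fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0229, adjusted p = 0.54 with an estimated correlation). There lmo2363, a glutamate decarboxylase gene, went from 2070 ± 1605 CPM in TSB to 47.2 ± 49 CPM in juice, at -5.46 ± 1.04, its neighbour lmo2362 changed by -6.36 ± 1.04 and lmo0037 by -2.80 ± 0.51. Of 18 biofilm and attachment genes 7 fell and 1 rose, or 8 and 1 adjusted over the list alone (adjusted p = 0.000262, adjusted p = 0.268 with an estimated correlation). The agr signalling locus genes lmo0049 and lmo0051 fell with -4.68 ± 0.49 and -3.74 ± 0.42, and lmo0527 with -1.83 ± 0.35.

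In the phage and monocin list, 9 of the 17 tested genes fell, 14 adjusted over the list alone (adjusted p = 9.84e-06, adjusted p = 0.637 with an estimated correlation). Examples were lmaB at -3.18 ± 0.75, lmo0126 at -3.20 ± 0.87 and lmo0120 at -2.96 ± 0.82. Of 17 purine synthesis genes 3 fell, also adjusted over the list alone (adjusted p = 0.0306, adjusted p = 0.449 with an estimated correlation). These were purF at -3.27 ± 0.66, purQ at -2.01 ± 0.57 and purH at -2.09 ± 0.61. The invasion protein genes inlA and inlB were lower in juice at -2.55 ± 0.61 and -2.13 ± 0.51 (adjusted p = 0.0157 and 0.0158), and the stress sigma factor gene sigB was higher at 2.34 ± 0.59 (adjusted p = 0.02). No change was called for prfA (lmo0200) at 0.03 ± 0.49, hly at 0.05 ± 0.64, plcA at 0.76 ± 0.49, actA at -0.58 ± 0.48, ldh at 1.17 ± 0.47, flaA at 1.38 ± 0.67 or eutB at 1.10 ± 0.71. The eutB transcript reached at most 1.079 CPM in any of the 10 libraries, so its missing calls here and below say little.

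With a term for the library class, 214 rows were called, and 146 within the high class, where TSB is 1 library. Of the 43 named genes called, 28 and 22 kept their call in these fits, and those of sigB, inlA, inlB and the chaperone, phage and purine examples were lost in both. Both fits set juice against TSB replicate 1 alone, whose spread other groups then supply, so they count as a single observation. With the class term the fold of sigB was 2.36 ± 0.99 (2.34 ± 0.59 without it) and that of groES 2.31 ± 0.84 (2.34 ± 0.50), so those calls ended through wider errors. The folds of inlA and inlB shrank to -1.62 ± 0.73 and -1.21 ± 0.60 as well. Within the high class the calls of lmo2361, lmo2829, lmo2580, lmo2363, lmo0037, lmo0527, eno, argG and trpF were also lost. Their folds there included -4.50 for lmo2363 (-5.46 in the main fit) and 4.60 for eno (4.01).

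The list counts in planktonic cells fell with the class term and within the high class. With that term the folds of the 43 named calls were a median of 1.01 times (0.57 to 1.24) the main values. Their standard errors were 1.32 times those (median). By edgeR the 9 phage genes became 0 in both (3 at an unadjusted p under 0.05 in each), the 6 chaperone genes 0 (4 and 2) and the 3 purine genes 0 (1 in each). Amino acid genes went from 11 risen and 2 fallen to 2 and 0, then 1 and 0, ribosomal proteins from 33 to 26 and 17, glycolysis from 9 to 7 and 4, attachment from 7 fallen to 3 and 2 and acid resistance from 5 fallen to 3 and 1. With the duplicated table as a cantaloupe biofilm or both copies, 1 or 3 phage genes, 1 purine gene in each and 7 or 5 risen amino acid genes were called. With the replicate block 14 phage genes and 6 purine genes fell, 1 acid resistance gene rose and no attachment gene did.

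The planktonic medium count was 1380 without juice replicate 3, 407 without juice replicate 2, 388 without TSB replicate 2 and 246 when fitted on the planktonic libraries alone. That last fit kept 31 of the 43 named calls. Without TSB replicate 2 the calls of lmaB, lmo0126, lmo0120, groEL, purQ, purH, inlA, inlB and sigB were lost (adjusted p = 0.0506 to 0.118). Those of lmo0126, inlB and sigB were also lost without juice replicate 2 (0.0535 to 0.0619), that of sigB without juice 1 (0.0566), TSB 1 (0.0611) or TSB 3 (0.0665), and those of lmo0120, purQ and purH without juice 1 (0.0612 to 0.0974). Fits without a biofilm library also ended named calls, but not all of these 3 in each such fit.

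Among the list calls in planktonic cells, acid resistance was lost without juice replicate 3 (adjusted p = 0.0854) and with the class term (0.0714), chaperones without juice replicate 1 (0.0541) or TSB replicate 3 (0.0536) and with the class term (0.135). That of purine synthesis was lost without juice replicate 3 (0.111) or TSB replicate 3 (0.0659), with the class term (0.244), and with the duplicated table as a cantaloupe biofilm (0.0521) or both copies (0.054). By fry, a list test of another null hypothesis, the amino acid (adjusted p = 0.0742) and chaperone (0.0622) calls were lost.

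**Figure D2:**
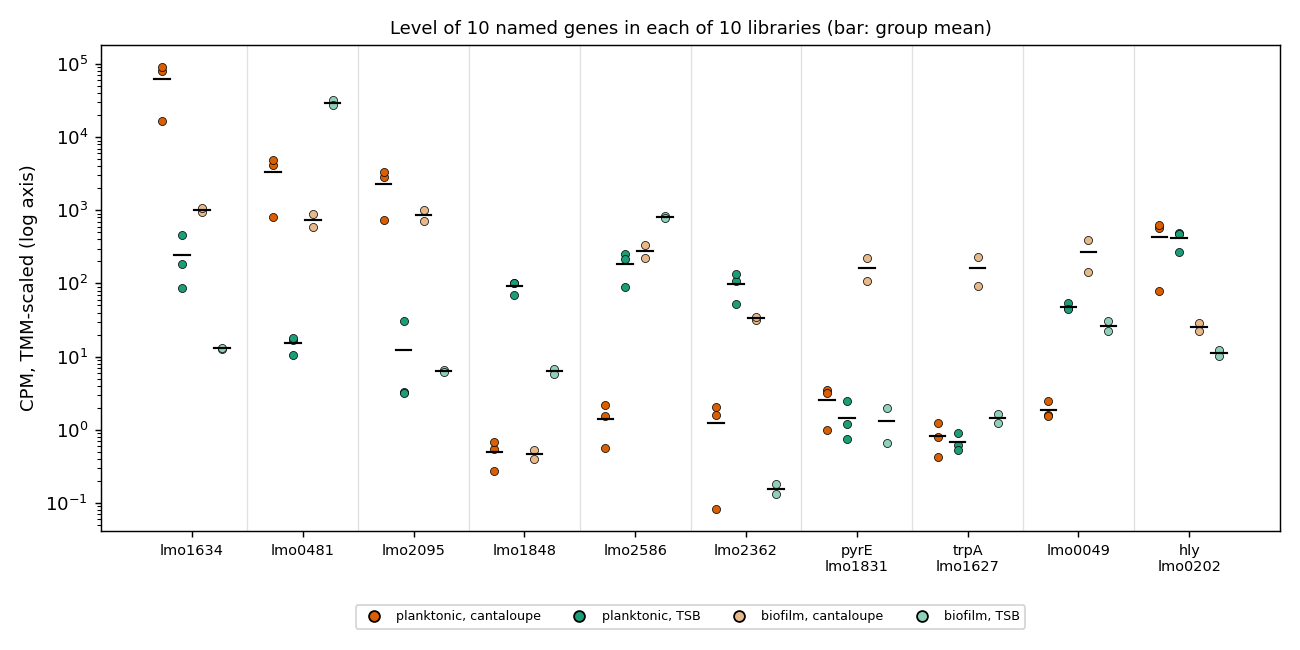
CPM on TMM-scaled library sizes (log y axis) of 10 named genes (x axis) in each of the 10 libraries, as points coloured by group, with a bar at each group mean. In planktonic cells lmo1634 averages 62860 in cantaloupe juice and 243 in TSB, and pyrE and trpA stand above 90 CPM only in the 2 cantaloupe biofilms.

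In biofilms, 8 of 11 pyrimidine synthesis genes, the tryptophan synthase gene trpA and 8 of 19 iron and heme uptake genes had higher transcript levels in cantaloupe juice than in TSB, and 1 of those 19 a lower one. The pyrE transcript stood at 165 ± 82.6 CPM in juice (n = 2) and 1.3 ± 0.917 CPM in TSB (n = 2), a log2 fold change of 6.99 ± 1.03 (adjusted p = 0.00776). The trpA transcript stood at 160.1 ± 96.7 CPM and 1.43 ± 0.294 CPM, at 6.80 ± 0.77 (adjusted p = 0.00594). In the other direction lmo0481 stood at 739 ± 201 CPM in juice and 29660 ± 3462 CPM in TSB, at -5.33 ± 0.96 (adjusted p = 0.0123). The edgeR test called 243 rows, 167 higher in juice and 76 lower, against 283 and 71 on log2(TPM + 1) values.

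Of 11 pyrimidine synthesis genes 8 rose, 9 adjusted over the list alone (camera adjusted p = 1.29e-08, adjusted p = 0.292 with an estimated correlation). Examples were pyrF at 6.66 ± 1.22, pyrDII at 6.34 ± 1.08 and pyrD at 6.15 ± 1.08. Of 19 iron and heme uptake genes 8 rose and 1 fell, or 9 and 2 adjusted over the list alone (adjusted p = 0.00317, adjusted p = 0.403 with an estimated correlation). The heme-binding protein gene lmo2185 rose by 7.40 ± 0.98, the ferrichrome transport gene fhuC by 4.60 ± 0.67 and lmo1961 by 3.92 ± 0.66. Of 42 flagella and chemotaxis genes 7 rose, 13 adjusted over the list alone (adjusted p = 0.000315, adjusted p = 0.626 with an estimated correlation). Examples were fliP at 7.72 ± 1.77 and cheA at 4.23 ± 0.73. Levels were low for lmo0708, at 4.78 ± 0.88, and for lmo0675, which had 1 read in all in the TSB biofilms, so no fold is given for it. The flagellin gene flaA itself was not called at 2.86 ± 0.86 (adjusted p = 0.0673).

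Of 56 ribosomal protein genes 6 rose in juice, and 22 adjusted over the list alone (adjusted p = 2.32e-07, adjusted p = 0.426 with an estimated correlation). Examples were rpsG at 2.59 ± 0.52, rpmF at 2.70 ± 0.55 and rplJ at 2.16 ± 0.46. Of 18 biofilm and attachment genes 5 rose, also adjusted over the list alone (adjusted p = 0.0189, adjusted p = 0.403 with an estimated correlation). They included lmo0049 at 3.35 ± 0.56 and dltB and dltC, which act in D-alanylation of lipoteichoic acid, at 3.75 ± 0.71 and 3.45 ± 0.64. In the purine list 1 of 17 rose, lmo1884 at 3.20 ± 0.78, and 5 adjusted over the list alone (adjusted p = 0.0399, adjusted p = 0.455 with an estimated correlation). In the competence list 1 of 10 rose, comGB at 4.62 ± 1.07, and 4 adjusted over the list alone (adjusted p = 0.0114, adjusted p = 0.311 with an estimated correlation). The comGB transcript stood at only 0.09498 and 0.03278 CPM in the TSB biofilms. Other large rises were lmo2362 at 7.73 ± 1.36, lmo2000 at 7.12 ± 0.94, lmo2095 at 7.10 ± 1.41 and lmo1634 at 6.31 ± 1.21.

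Lower in juice biofilms were lmo0482 at -6.39 ± 0.87, lmo2210 at -6.46 ± 1.66, lmo2203 at -5.51 ± 0.61, lmo2200 at -4.95 ± 0.74, lmo0758 at -4.88 ± 0.77 and the neighbours lmo0266, lmo0267 and lmo0268 at -4.66 ± 0.85, -4.44 ± 0.83 and -3.94 ± 0.69. Of 19 internalin genes 3 fell, or 7 with 1 rise adjusted over the list alone (adjusted p = 0.00201, adjusted p = 0.292 with an estimated correlation). These were lmo1290 at -2.60 ± 0.48, lmo0331 at -2.90 ± 0.75 (-2.60 with the replicate block, adjusted p = 0.054) and inlB at -2.40 ± 0.63. In the SigB stress list 2 of 55 fell and 1 rose, or 1 each adjusted over the list alone (adjusted p = 0.000865, adjusted p = 0.798 with an estimated correlation). Examples were lmo2386 at -2.63 ± 0.47 and lmo0796 at -1.47 ± 0.38. Only lmo2199, at -4.29 ± 0.69, fell of 11 oxidative stress genes, also adjusted over the list alone (adjusted p = 0.00368, adjusted p = 0.637 with an estimated correlation). In the phage list 1 of 17 fell, lmaC at -2.55 ± 0.68, and 2 adjusted over the list alone (adjusted p = 1.12e-05, adjusted p = 0.637 with an estimated correlation). No call was made for sigB at -0.12 ± 0.69, inlA at -2.04 ± 0.73, prfA (lmo0200) at -1.13 ± 0.60, plcA at -0.19 ± 0.60, hly at 1.18 ± 0.80, actA at 1.76 ± 0.61, ldh at -1.22 ± 0.57 or eutB at -0.34 ± 0.79.

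These calls depend on how the duplicated table is used, since no gene was called by edgeR when it counted as a cantaloupe biofilm (465 at an unadjusted p under 0.05) or when both copies were kept (380), while 307 were called when it counted as a TSB biofilm. In the first fit the 41 named folds were a median of 0.87 times (-0.49 to 1.2) the main values. Their standard errors were 1.42 times those (median). With both copies the medians were 0.68 and 1.24 (40 calls). The table held lmo1634 at 42.9 per M protein-coding reads, against 37.7 and 38.6 in TSB and 5130 and 5337 in juice biofilms. The fits with 0 calls thus put a table TSB-like in lmo1634 among juice biofilms. For the protease gene clpE that table exceeded all other biofilms. With the class as a term edgeR called 0 (379 at an unadjusted p under 0.05). The class then takes its estimate from planktonic TSB replicate 1 alone, and over the 41 named calls the fold was 1.05 times and the standard error 1.48 times the value without the term (medians), so this fit cannot tell whether the calls depend on the class. Without 1 library the count was 31 or 23 (juice biofilm 1 or 2), 0 or 1 (TSB biofilm 2 or 3, with 382 or 428 at an unadjusted p under 0.05) and 892 (planktonic juice 3), and it was 1529 on the biofilm libraries alone and 467 by DESeq2.

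With the replicate block the biofilm medium counts were 13 risen ribosomal protein genes, 9 fallen phage genes, 8 fallen SigB genes, 3 risen purine genes, 2 risen competence genes, and 2 fallen genes each for oxidative stress and iron uptake. The biofilm medium call of the purine list was lost with the replicate block (adjusted p = 0.0501), with the duplicated table as a cantaloupe biofilm (0.336), and without juice biofilm 1 (0.0877), TSB biofilm 3 (0.0732), planktonic juice 3 (0.0543) or planktonic TSB 1 (0.0711). That of the attachment list was lost with the block (0.076) and that table as a cantaloupe biofilm (0.133), internalins with that table so used (0.0851), iron and heme uptake with the strict filter (0.109), and competence with that filter (0.0696), the class term (0.17) or without planktonic juice 3 (0.074). By fry the biofilm medium calls of SigB (adjusted p = 0.296), phage (0.143) and oxidative stress (0.0898) genes were lost.

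Within cantaloupe juice, where every library is of the high class, 9 of 11 pyrimidine synthesis genes, trpA and the agr locus gene lmo0049 had higher transcript levels in biofilms than in planktonic cells. Lower in biofilms were 17 of 21 glycolysis and fermentation, 31 of 56 ribosomal protein and 8 of 13 chaperone genes. The lmo0049 transcript stood at 271 ± 181 CPM in biofilms (n = 2) and 1.87 ± 0.549 CPM in planktonic cells (n = 3), a log2 fold change of 7.18 ± 0.56 (adjusted p = 0.000138). The pflA (lmo1917) transcript stood at 226 ± 12.3 CPM in biofilms and 10270 ± 5917 CPM in planktonic cells, at -5.50 ± 0.87 (adjusted p = 0.00162). The edgeR test called 964 rows, 539 higher in biofilms and 425 lower, against 792 and 179 on log2(TPM + 1) values and 517 and 628 by DESeq2.

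The largest rises were lmo2839 and lmo2838, of a sugar ABC transporter, at 10.48 ± 0.94 and 7.87 ± 0.81, both from under 0.1 CPM in planktonic cells. Next came lmo0027 at 7.83 ± 0.46, lmo2586 and lmo2584 of the formate dehydrogenase cluster at 7.66 ± 0.74 and 7.32 ± 0.67, lmo2102 at 7.35 ± 0.51 and lmo0604 at 7.35 ± 0.51. Of 11 pyrimidine synthesis genes 9 rose, also adjusted over the list alone (camera adjusted p = 7.02e-05, adjusted p = 0.426 with an estimated correlation). Examples were pyrF at 7.25 ± 1.05, pyrDII at 7.05 ± 0.93, pyrD at 6.91 ± 0.93 and pyrE at 6.04 ± 0.82. Of 17 purine synthesis genes 8 rose, or 10 with 1 fall adjusted over the list alone (adjusted p = 0.0114, adjusted p = 0.403 with an estimated correlation). Examples were purH at 5.07 ± 0.71, purD at 4.89 ± 0.77 and purN at 4.11 ± 0.68. Of 56 amino acid genes 16 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.0191, adjusted p = 0.719 with an estimated correlation). Here trpA rose by 7.64 ± 0.67, trpF by 6.01 ± 0.72 and trpE by 5.66 ± 0.58, while argH and argG fell with -5.99 ± 0.90 and -5.54 ± 0.86.

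Of 18 biofilm and attachment genes 13 rose and none fell, 14 adjusted over the list alone (adjusted p = 9.41e-06, adjusted p = 0.209 with an estimated correlation). Examples were lmo0051 at 3.24 ± 0.44 and lmo0528 at 3.17 ± 0.41. In the SigB stress list 17 of 55 rose and 5 fell, or 20 and 6 adjusted over the list alone (adjusted p = 0.0191, adjusted p = 0.817 with an estimated correlation). Examples were lmo0555 at 4.86 ± 0.42, inlH at 4.68 ± 0.57 and rsbT at 3.79 ± 0.46. The sigB gene itself was not called at -0.36 ± 0.64.

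Of 21 glycolysis and fermentation genes 17 fell and 1 rose, also adjusted over the list alone (adjusted p = 4.46e-08, adjusted p = 0.511 with an estimated correlation). Examples were pflB at -4.43 ± 0.67, pflC at -5.49 ± 0.83 and lmo1634 at -5.94 ± 1.17. Of 56 ribosomal protein genes 31 fell, 34 adjusted over the list alone (adjusted p = 1.14e-07, adjusted p = 0.403 with an estimated correlation). Examples were rpmJ at -3.29 ± 0.47 and rplD at -2.49 ± 0.43. Of 13 chaperone genes 8 fell, also adjusted over the list alone (adjusted p = 0.000552, adjusted p = 0.548 with an estimated correlation). Examples were groES at -4.45 ± 0.66, grpE at -4.06 ± 0.69 and the repressor gene hrcA at -4.40 ± 0.54. Of the 11 genes of the PrfA virulence list, 1 of them the release factor gene lmo2543, 5 others fell, 6 adjusted over the list alone (adjusted p = 0.0399, adjusted p = 0.626 with an estimated correlation). The listeriolysin O gene hly changed by -4.06 ± 0.86, plcA by -3.98 ± 0.66, inlB by -3.03 ± 0.62 and actA by -1.64 ± 0.57. In the phage list 2 of 17 fell, lmaD at -3.46 ± 0.78 and lmaC at -2.92 ± 0.67, also adjusted over the list alone (adjusted p = 0.0338, adjusted p = 0.817 with an estimated correlation). Other large falls were lmo2580 at -5.98 ± 0.87, lmo2581 at -5.76 ± 0.70 and lmo0752 at -5.80 ± 0.79. The sizes of 4 more falls came from planktonic juice replicate 3, namely ftsE at -6.95 ± 2.20, lmo0514 at -6.39 ± 2.01, lmo1250 at -5.81 ± 1.47 and gbuA at -5.61 ± 1.49. Without it they were -2.58, -2.37, -3.055 and -3.17, all still called. With the replicate block ftsE was -3.79 (adjusted p = 0.0865) and lmo0514 -3.35 (0.0853), neither called. No call was made for prfA (lmo0200) at -1.38 ± 0.57, inlA at -0.31 ± 0.65, ldh at -0.51 ± 0.52, flaA at 0.31 ± 0.73 or eutB at -1.41 ± 0.76.

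The count was 387 or 470 without juice biofilm 1 or 2, 1482 without planktonic juice 3 and 586 on the juice libraries alone. All 48 named genes called kept their call without planktonic juice 3, 47 kept it with the class as a term and 43 on the juice libraries alone. With the duplicated table as a cantaloupe biofilm 4 lost it, namely lmo0514 at -2.67 ± 1.72 (adjusted p = 0.24), lmaD at -2.05 ± 0.83 (0.0732), lmaC at -1.77 ± 0.72 (0.0732) and inlB at -1.02 ± 0.85 (0.365), and the same 4 lost it with both copies. Without juice biofilm 1 or 2 the calls of ftsE, lmo0514, lmo1250, gbuA, lmo1634, lmaD, lmaC, inlB, hly and actA were lost (adjusted p = 0.052 to 0.25), those of ftsE and lmo0514 also without TSB biofilm 2 or 3, and that of actA without any library but planktonic juice 3.

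With the replicate block 7 phage genes fell and 1 PrfA gene rose between growth forms in juice. On log2(TPM + 1) values the list medians shrank from -2.37 to -0.41 for ribosomal proteins, from -1.64 to -0.25 for PrfA genes and from -1.90 to -0.19 for phage genes. The juice growth form call of the SigB list was lost with the replicate block (adjusted p = 0.0752), by fry (0.107) and without planktonic juice 3 (0.348). That of amino acid genes was lost without juice biofilm 1 (0.0966) or planktonic juice 3 (0.0833), PrfA genes without planktonic juice 1 (0.0688) or 2 (0.0611) and with the strict filter (0.0522), and phage genes without planktonic juice 1 or 2 (0.139 each). With the duplicated table as a cantaloupe biofilm or both copies, purine (0.156 and 0.162) and phage (0.45 and 0.466) calls were lost. The phage call was also lost by fry (0.317).

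In TSB, 26 of 55 SigB stress genes and 24 of 56 amino acid synthesis genes had higher transcript levels in biofilms than in planktonic cells. Lower in biofilms were 6 of 10 PrfA virulence genes, 6 of 11 zinc and manganese uptake genes and the pyruvate dehydrogenase genes pdhA and pdhC. The lmo0481 transcript rose from 15.2 ± 4.06 CPM in planktonic cells (n = 3) to 29660 ± 3462 CPM in biofilms (n = 2), a log2 fold change of 10.94 ± 1.00 (adjusted p = 0.000791). The hly transcript stood at 412 ± 126 CPM in planktonic cells and 11.3 ± 1.68 CPM in biofilms, at -5.19 ± 0.92 (adjusted p = 0.00538). The edgeR test called 547 rows, 334 higher in biofilms and 213 lower. The split was 245 and 246 with upper-quartile factors, 675 and 52 on log2(TPM + 1) values, and 378 and 422 by DESeq2.

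Of 55 SigB stress genes 26 rose and 2 fell, 33 and 2 adjusted over the list alone (camera adjusted p = 5.19e-09, adjusted p = 0.626 with an estimated correlation). Examples were lmo0602 at 4.98 ± 0.57, lmo0555 at 3.81 ± 0.40, lmo0796 at 3.43 ± 0.34 and sigB itself at 2.10 ± 0.63 (adjusted p = 0.0429). Of 19 internalin genes 7 rose and 1 fell, or 7 and 2 adjusted over the list alone (adjusted p = 0.0207, adjusted p = 0.403 with an estimated correlation). Examples were inlH at 4.20 ± 0.56, lmo0610 at 3.44 ± 0.59 and lmo0732 at 3.22 ± 0.49. Of 56 amino acid genes 24 rose, or 25 with 1 fall adjusted over the list alone (adjusted p = 8.7e-05, adjusted p = 0.586 with an estimated correlation). Examples were dapA at 3.41 ± 0.59, trpE at 3.58 ± 0.55 and hisH at 3.89 ± 0.68. The trpE and hisH transcripts were very low in planktonic TSB cells, with at most 0.5988 and 0.1553 CPM in a library. Other large rises were lmo0482 at 6.73 ± 0.74, lmo0987 and lmo0986 at 6.06 ± 0.74 and 5.22 ± 0.57, lmo1140 at 5.05 ± 0.60, lmo0269 at 5.02 ± 0.47, lmo2269 at 4.86 ± 0.73, lmo2708 at 4.77 ± 0.65 and the NAD synthesis gene nadA at 4.63 ± 0.52.

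Of the 11 genes of the PrfA virulence list as written 7 fell, 1 of them the release factor gene lmo2543, so 6 of 10 without it. The 7 were also found adjusted over the list alone (adjusted p = 8.22e-05, adjusted p = 0.31 with an estimated correlation). Examples were mpl at -4.92 ± 0.94, actA at -3.98 ± 0.65, plcA at -3.04 ± 0.62, plcB at -2.77 ± 0.46 and inlB at -2.76 ± 0.61. Of 11 zinc and manganese uptake genes 6 fell, also adjusted over the list alone (adjusted p = 6.28e-06, adjusted p = 0.268 with an estimated correlation). Examples were lmo1849 at -7.25 ± 0.84, lmo1848 at -3.86 ± 0.54 and the manganese transporter gene lmo1424 at -6.25 ± 0.78. Of 21 glycolysis and fermentation genes 10 fell and 3 rose, 11 and 4 adjusted over the list alone (adjusted p = 0.00163, adjusted p = 0.719 with an estimated correlation). The pyruvate dehydrogenase genes pdhA and pdhC fell with -4.75 ± 0.65 and -5.30 ± 0.81 and pflA with -5.99 ± 0.89, while the lactate dehydrogenase gene ldh rose by 1.89 ± 0.51 (adjusted p = 0.0296). The largest falls also held lmo1250 at -10.44 ± 1.89, lmo2362 at -9.29 ± 1.43, lmo2363 at -7.74 ± 1.40 and lmo0897 at -5.83 ± 0.81. The lmo1250 transcript stood at only 0.02374 and 0.03278 CPM in the TSB biofilms. The size of its fall thus rests on very few reads and is uncertain.

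Of 42 flagella and chemotaxis genes 8 fell and 1 rose, 15 and 4 adjusted over the list alone (adjusted p = 0.00495, adjusted p = 0.657 with an estimated correlation). Examples were fliG at -4.40 ± 0.81, lmo0700 at -4.87 ± 0.88 and, upward, lmo0674 at 3.02 ± 0.46. Of 13 chaperone genes 3 fell, 7 adjusted over the list alone (adjusted p = 0.00582, adjusted p = 0.637 with an estimated correlation). These were hrcA at -2.68 ± 0.49, groES at -2.41 ± 0.59 and grpE at -2.33 ± 0.63. Of 56 ribosomal protein genes 6 fell and 1 rose, 3 and 1 adjusted over the list alone (adjusted p = 0.000994, adjusted p = 0.637 with an estimated correlation), and their median of -1.14 turned to 0.24 on log2(TPM + 1) values. On those values the medians of flagella genes (-1.65), PrfA genes (-2.76) and glycolysis genes (-1.26) shrank to -0.07, -0.54 and -0.36. Examples were rplJ at -2.47 ± 0.45, rpsN (lmo1882) at -2.72 ± 0.58 and, upward, rpsK at 1.75 ± 0.43. In the phage list 2 of 17 fell, lmaC at -2.29 ± 0.65 and lmaB at -2.86 ± 0.87, or 14 with 1 rise adjusted over the list alone (adjusted p = 0.0037, adjusted p = 0.762 with an estimated correlation). No call was made for prfA (lmo0200) at -0.21 ± 0.55, inlA at -0.82 ± 0.66, flaA at -1.17 ± 0.76 or eutB at 0.03 ± 0.78.

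The count was 352 when the duplicated table counted as a cantaloupe biofilm, 111 or 143 without TSB biofilm 2 or 3, 353 or 351 without juice biofilm 1 or 2, 308 without planktonic TSB 2, 1258 without planktonic juice 3 and 1001 on the TSB libraries alone. Without planktonic TSB 1, which leaves libraries of the low class alone, it was 410. Without TSB biofilm 2, 24 named calls were lost and without TSB biofilm 3, 19, among them hly, actA, plcA, inlB, lmo2363, rplJ, groES, ldh and sigB in both (adjusted p = 0.0519 to 0.195). The calls of ldh and sigB were also lost without juice biofilm 1 or 2 or any planktonic TSB library (0.0602 to 0.11). With the replicate block 15 ribosomal protein genes fell and 2 rose between growth forms in TSB, 4 phage genes fell and 1 rose, 2 flagella genes rose and 1 amino acid gene fell. With the duplicated table as a cantaloupe biofilm 13 amino acid genes and 4 internalin genes rose and 3 flagella and 4 ribosomal protein genes fell, and 6 of the 48 named calls were lost, as with both copies. The TSB growth form call of the internalin list was lost without planktonic TSB 1 (0.0543), with the class term (0.055) and with the duplicated table as a cantaloupe biofilm (0.0521), and that of chaperones with it as a TSB biofilm (0.154) or both copies (0.163). By fry the calls of phage (adjusted p = 0.207), flagella (0.107), glycolysis (0.107), ribosomal protein (0.0735) and chaperone (0.0577) genes were lost.

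The medium effect differed between growth forms for 296 rows in the edgeR interaction test, 168 with a more positive juice effect in biofilms and 128 with a more negative one. The split was 188 and 92 with upper-quartile factors, 233 and 247 by DESeq2, 178 and 189 with the replicate block, and 18 and 28 or 30 and 37 without TSB biofilm 2 or 3, so which direction holds more genes is not settled. The acid resistance transcript lmo2362 was lower in juice in planktonic cells and higher in juice in biofilms, a difference on the log2 scale of 14.09 ± 1.78 (adjusted p = 0.00318). The lmo0481 transcript was higher in juice in planktonic cells and lower in biofilms, at -13.09 ± 1.37 (adjusted p = 0.00176). Next came lmo2839 at 12.27 ± 1.25, lmo1999 at 10.07 ± 1.30, lmo2838 at 9.95 ± 1.10 and lmo2363 at 8.70 ± 1.60 upward, and lmo0482 at -7.98 ± 1.02, lmo0266 at -7.77 ± 1.08, lmo0758 at -7.73 ± 0.97 and lmo2203 at -7.30 ± 0.74 downward.

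Camera called 10 lists in the interaction. Of 11 pyrimidine genes 8 differed upward, 9 adjusted over the list alone (adjusted p = 1.57e-07, adjusted p = 0.292 with an estimated correlation). Examples were pyrD at 8.33 ± 1.30, pyrDII at 6.60 ± 1.24 and pyrE at 6.18 ± 1.13. Of 18 biofilm and attachment genes 7 differed upward, 9 adjusted over the list alone (adjusted p = 3.73e-06, adjusted p = 0.209 with an estimated correlation). Examples were lmo0049 at 8.04 ± 0.77, dltB at 5.98 ± 0.90 and dltC at 5.44 ± 0.81. Upward as well were 5 of 11 zinc and manganese genes, also adjusted over the list alone (adjusted p = 0.00054, adjusted p = 0.311 with an estimated correlation). Examples were lmo1849 at 6.39 ± 0.94, lmo1424 at 4.84 ± 0.87 and lmo1848 at 3.77 ± 0.68. Of 17 purine genes 5 differed upward, 6 adjusted over the list alone (adjusted p = 0.000997, adjusted p = 0.292 with an estimated correlation), and purF stood at 5.09 ± 1.02. Flagella genes differed upward in 5 of 42, or 7 with 1 downward adjusted over the list alone (adjusted p = 0.00325, adjusted p = 0.637 with an estimated correlation), and cobalamin genes in 4 of 22, also adjusted over the list alone (adjusted p = 0.0302, adjusted p = 0.548 with an estimated correlation). Examples were fliQ at 5.65 ± 1.40 (4.25 with the replicate block, adjusted p = 0.0821) and cbiH at 5.09 ± 0.95.

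Downward, 5 of 21 glycolysis genes differed, 6 adjusted over the list alone (adjusted p = 0.00549, adjusted p = 0.742 with an estimated correlation). Examples were gap at -6.40 ± 1.04, pgm at -6.42 ± 1.07 and pgk at -5.68 ± 0.88. In the SigB list 6 of 55 differed downward and 2 upward, 10 and 2 adjusted over the list alone (adjusted p = 0.0235, adjusted p = 0.817 with an estimated correlation), and lmo0796 stood at -3.34 ± 0.49. Of 11 oxidative stress genes lmo2199 differed downward at -5.67 ± 0.84, 3 adjusted over the list alone (adjusted p = 0.00252, adjusted p = 0.637 with an estimated correlation). Of 56 ribosomal protein genes 3 differed downward and none adjusted over the list alone (adjusted p = 0.0048, adjusted p = 0.637 with an estimated correlation). These were rpsM at -2.75 ± 0.61, rpsK at -2.39 ± 0.62 and rpmJ at -2.15 ± 0.58 (-2.08 with the replicate block, adjusted p = 0.0531). None of the well-known genes was called, with prfA (lmo0200) at -1.16 ± 0.77, hly at 1.13 ± 1.02, inlA at 0.51 ± 0.91, inlB at -0.27 ± 0.77 and sigB at -2.46 ± 0.91.

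The interaction count was 126 when the duplicated table counted as a cantaloupe biofilm, 170 with both copies and 182 with the class as a term. Of 36 named calls 17 were kept with the table as a cantaloupe biofilm, and 20 of 35 with both copies. In the first of these fits edgeR called 0 of the pyrimidine genes (9 at an unadjusted p under 0.05), purine genes (6), flagella genes (12) and cobalamin genes (4), against 3, 1, 1 and 1 with both copies. As a cantaloupe biofilm it left pyrD at 7.77 ± 2.01 (adjusted p = 0.0526) and pyrE at 5.61 ± 2.11 (0.142), but lmo0482 at -4.25 ± 1.78 (0.186), lmo0758 at -2.63 ± 2.02 (0.486) and lmo2203 at 0.17 ± 2.40 (0.983). Without 1 library it was 72 or 83 (juice biofilm 1 or 2), 46 or 67 (TSB biofilm 2 or 3), 181 (planktonic TSB 1) and 1089 (planktonic juice 3), and it was 480 by DESeq2. Of the genes named, those of the purine, flagella and ribosomal lists lost their call without juice biofilm 1, TSB biofilm 2 or TSB biofilm 3, and gap, pgm and pgk without juice biofilm 1 or 2 (adjusted p = 0.0526 to 0.0683).

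With the replicate block the interaction counts were 8 zinc and manganese genes, 3 flagella genes and 3 ribosomal protein genes upward, and 10 SigB, 2 ribosomal protein and 2 oxidative stress genes downward. The interaction call of the cobalamin list was lost with the replicate block (adjusted p = 0.173), the strict filter (0.867), the class term (0.0781), the duplicated table as a cantaloupe biofilm (0.0926) or both copies (0.0556). It was also lost without juice biofilm 2 (0.0517), planktonic juice 3 (0.273) or planktonic TSB 1 (0.11). That of ribosomal proteins was lost with the block (0.0741), the class term (0.0581) and without planktonic TSB 1 (0.0586), and flagella with the strict filter (0.1) and without planktonic juice 3 (0.155). The SigB call was lost without planktonic juice 1 (0.176), juice 2 (0.112) or TSB 3 (0.0799), with the duplicated table as a TSB biofilm (0.0899) and with both copies (0.118). By fry the interaction calls of SigB (adjusted p = 0.444), glycolysis (0.199), ribosomal protein (0.116), flagella (0.0742) and oxidative stress (0.0742) genes were lost.

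**Figure D3:**
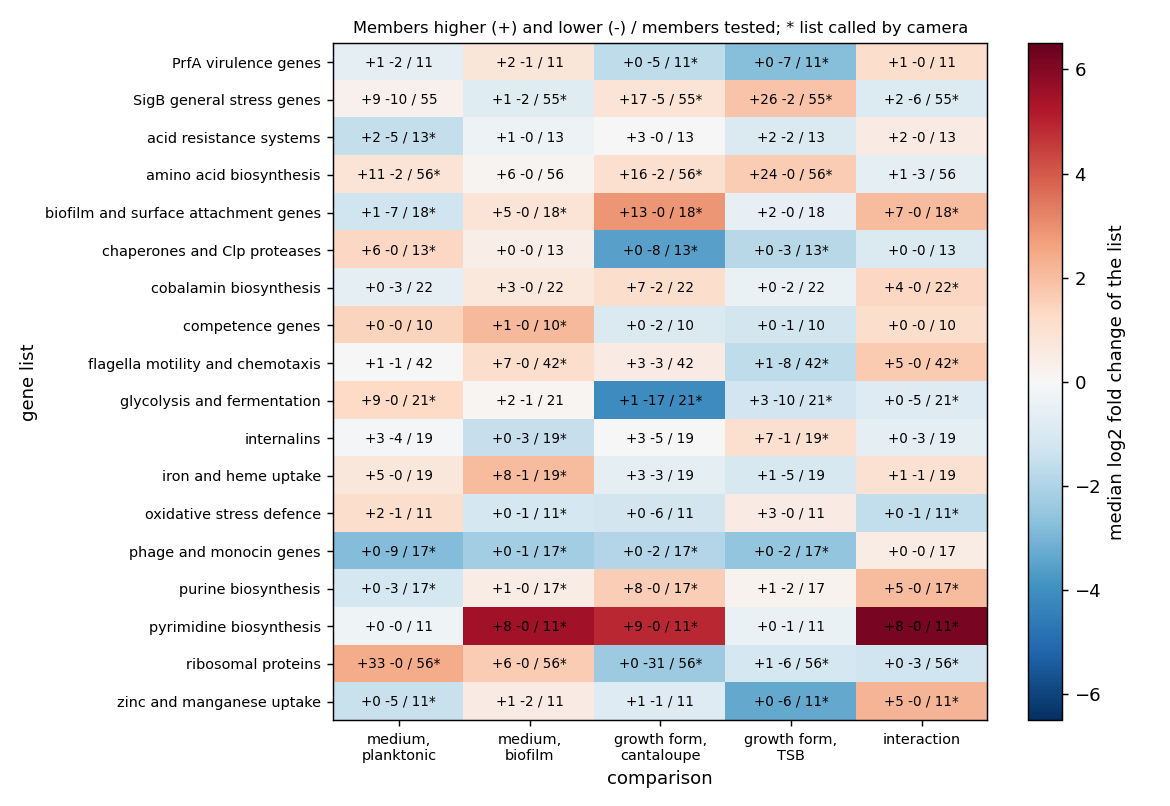
Gene lists called in at least 1 comparison (y axis) in each of the 5 comparisons (x axis), coloured by the list's median log2 fold change. Cells give members called higher (+) and lower (-) over members tested, and an asterisk marks a camera call, as for ribosomal proteins with 33 of 56 genes higher in planktonic juice cells.

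Across the 2668 rows, the medium effects in planktonic cells and in biofilms correlated with Spearman 0.194 and Pearson 0.214, over genes, which are not independent replicates. These 2 comparisons share no library. They had 106 rows called in both, 38 higher in juice in both against 21.8 for independent lists and 27 lower in both against 8. Opposite calls were 15 higher in planktonic and lower in biofilm juice cells against 9.9, and 26 the other way against 17.6. Both comparisons use the same estimate of each gene's spread, so genes of low spread are called more readily in both. Counts in the same and in opposite directions alike exceeded those for independent lists. The excess alone therefore does not mark a shared response. Of the 296 interaction rows, 240 had medium effects of opposite sign, and 41 were called in opposite directions in both growth forms. The genes lmo1634 and lmo2095 were higher in juice in both growth forms.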

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

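The tests of explanations, that on other splits included, were chosen after the results had been seen, and the interaction test was chosen before.

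The medium effect differed between growth forms by the interaction test for 296 rows, and the 10 named ones drew attention by that test. Upward they were lmo2362 (log2 14.09), lmo2839 (12.27), lmo1999 (10.07), lmo2838 (9.95) and lmo2363 (8.70), and downward lmo0481 (-13.09), lmo0482 (-7.98), lmo0266 (-7.77), lmo0758 (-7.73) and lmo2203 (-7.30). In rows that the comparisons do not use, rRNA still held up to 9.12% of reads in a library and tRNA up to 0.102%. The table deposited under 2 names, which no main comparison uses, held 47.7 M reads.

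The 4 small RNA rows that split the libraries into classes differed by a median of 8.52 on the log2 scale between high and low libraries, per protein-coding read. Lower recovery of all small RNAs in the low libraries would move the other rows about as much, but the median of the 45 other small RNA rows was 2.49 and that of 31 tRNA rows was -0.54. The tRNA median argues against it. The 4 rows, at 7.48 to 9, define the classes, so a lower median in the other small RNA rows is partly built in. Those other rows ranged from -3.1 to 8.9, so the shift was not confined to the 4. The growth medium is a biological candidate explanation that stays open, because planktonic TSB replicate 1 held 28.7% on these rows against it, but is 1 library. RNA of a planktonic juice library in that TSB library is argued against, since the 4 rows would need a mixing share of 136%, more than a whole library. With the share capped at 100%, the needed level is that of planktonic juice itself. The 14 genes far higher in planktonic juice than in TSB replicates 2 and 3 stood at a median of 0.0274 of that level. A difference in library preparation or depletion between batches was not tested, as the labels give no batch.

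Planktonic juice replicate 3 stood apart from replicates 1 and 2. Per protein-coding read, without TMM scaling, 536 protein-coding genes were over 8 times higher in it and 2 over 8 times lower. TMM lowered its values more, so this imbalance depends on the scaling and was not counted on CPM values. For lmo1634, TMM took replicate 3 from 64582 per M protein-coding reads to 16440 CPM. Replicates 1 and 2 went from 111235 and 155638 to 80180 and 91950. A mixture with another library here is argued against by 30 protein-coding genes, which in replicate 3 exceeded every other library over 5 times on the same scale. Lower depth is argued against by the 18.5 M protein-coding reads of replicate 3, the most of the 3. Its deviation from the group mean correlated with that of TSB replicate 3 at 0.572 across genes, against -0.106 and -0.526 with TSB replicates 1 and 2, so a shared experiment or day may be a cause, though deviations of 3 libraries sum to about 0 and these values are not independent. No biological explanation was tested, since the labels name no difference among these 3 cultures.

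For the planktonic medium effect, 1 of the 10 splits of the 6 libraries, the real one, gave 629 rows, and the highest other split gave 0 by edgeR. At an unadjusted p under 0.05 the real split gave 962 rows and the other splits 26 to 937. The split with 937 sets juice replicates 1 and 2 with TSB replicate 2 against juice replicate 3 with TSB replicates 1 and 3. What that split follows was not separated, since those that set juice replicates 1 and 2 with TSB replicate 1 or 3 instead gave 754 and 233. The 3 other splits that part all 3 same-numbered pairs gave 0 as well, with 233, 26 and 75 at an unadjusted p, against up to 937 for those that part 1 pair. With 10 splits no share under 0.05 can be reached.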

How the results depend on the processing

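The uses of the duplicated table, protein-coding rows alone, the class term, the high class comparison, the lists without homonyms and list tests under other fits were chosen after seeing the data. Other scalings, filters, tools and rows, where not given here, kept each count within 1.5 times. The cause of the changes was not tested, and fits on fewer libraries called fewer genes in some comparisons and more in others.

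The planktonic medium count of 629 became 246 on the planktonic libraries alone, 214 with the class term and 146 in the high class, and ranged from 388 to 1380 without 1 library. The biofilm medium count of 243 became 467 by DESeq2, 1529 on the biofilm libraries alone, and 0 with the duplicated table as a cantaloupe biofilm, with both copies, or with the class term, which in biofilms rests on planktonic TSB 1 alone, and ranged from 0 to 892 without 1 library. The growth form count in juice of 964 became 586 on the juice libraries alone and ranged from 387 to 1482. That in TSB of 547 became 1001 on the TSB libraries alone and 352 with the duplicated table as a cantaloupe biofilm, and ranged from 111 to 1258. The interaction count of 296 became 480 by DESeq2, 126 with the table as a cantaloupe biofilm, 170 with both copies and 182 with the class term, and ranged from 46 to 1089. Where a biofilm group kept 1 library, that library was assumed to vary like the other groups. The 892 in biofilms and the 1258 in TSB came without planktonic juice 3, a library in neither comparison. The main counts of 243 and 547 thus depend on a library of another group through the shared fit.

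The 50 list calls became 0 with an estimated correlation, 45 by fry (33 of the 50 kept and 12 new, in a test of another null hypothesis), 47 with the replicate block (45 kept and 2 new) and 50 without the homonyms (all kept), and ranged from 43 to 54 without 1 library. The Spearman correlation of 0.194 was 0.163 with the replicate block, 0.164 on protein-coding rows and 0.353 with the class term, and ranged from 0.146 to 0.227 without 1 library. In the class fit both effects share the class estimate of the planktonic TSB libraries, so 0.353 holds a built-in correlation and is not read.

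The replicate block gave 687 planktonic and 343 biofilm medium calls, 1017 and 719 growth form calls in juice and TSB and 367 interaction calls, each within 1.5 times the unblocked count, while counts within gene lists moved further where the report gives them. Beyond the calls given in the report as lost with it, the block ended those of lmo2543 between growth forms in TSB (-1.28, adjusted p = 0.0533) and cbiA in the interaction (3.25, 0.0787), and it ended no other named or list call. Its 2 new list calls concern nothing described as called or uncalled in the report. Over all rows the calls changed more than the counts. The unblocked fit shared 598 of the 687 planktonic and 201 of the 343 biofilm medium calls, and 905 of the 1017 growth form calls in juice. With the duplicated table as a cantaloupe biofilm, biofilm medium values reversed for lmo2203 (1.955), lmo0758 (0.21), lmo1290 (0.55) and lmo0331 (1.42), none past the threshold, and the interaction of lmo2203 became 0.17. On log2(TPM + 1) values many list medians shrank, and rpsU reversed between growth forms in juice (0.06). Of named genes called, 22 of 43, 0 of 41, 35 of 48, 23 of 48 and 9 of 36 kept their call in every fit, in the order of the 5 comparisons.

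Scaling moved the median gene by over 0.1 with upper-quartile factors (-0.18 planktonic, -0.19 growth form in TSB, 0.22 interaction), with DESeq2 factors (-0.17 growth form in juice, -0.12 interaction) and on TPM values (0.20, 0.31, 0.92 and 0.86 in the first 4 comparisons), so small changes of whole lists are relative to these shifts. Depth limits only genes near 0 counts.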

Other observations

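Several gene lists had no camera call in any comparison. For the planktonic medium effect, 4 of 25 tested propanediol utilization genes fell and 2 rose, and 3 of 8 glycerol genes fell. Growth form in juice had 3 of 17 ethanolamine genes lower, 5 propanediol genes higher and 1 lower, 2 of 9 ATP synthase genes higher, 2 of 12 SOS response genes higher, and 1 of 13 sugar phosphotransferase genes higher and 1 lower. Of 11 cold shock and osmolyte genes, 4 rose and 3 fell there. Of all 2668 rows, 348 rose and 281 fell in the planktonic medium effect. Between growth forms in juice 539 rows rose and 425 fell. Beside these shares, the counts above do not by themselves mark a change of a list.

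The protease gene clpE (lmo0997), chosen after its values were seen, held a large part of the protein-coding reads. It was lower in biofilms than in planktonic cells in juice by edgeR (log2 -3.51 ± 1.02, adjusted p = 0.0239) and not called in TSB (-2.55 ± 0.97, adjusted p = 0.0856). In the biofilm table deposited under 2 names, which both comparisons leave out, it held 247984 counts per 1e6 protein-coding reads, against 23840 and 35940 in the 2 juice biofilms used and 89346 to 173342 in planktonic juice libraries. The 2 TSB biofilms used held 20841 and 25978 and the planktonic TSB libraries 94971 to 254712, so that table stood above the biofilms of either medium. The small RNA row lmos81, also chosen afterwards, was lower in juice than in TSB in planktonic cells (-4.73 ± 1.10, adjusted p = 0.0145) and not called in biofilms (-3.22 ± 1.26, adjusted p = 0.136).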
